A study of Nematostella vectensis with 84 samples.

How the data were processed

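The samples were 84 RNA libraries from the oral disc and tentacles of adult starlet sea anemones, Nematostella vectensis. Each library belonged to 1 of 3 treatments and 1 time point, giving 14 groups of 6 libraries that the labels name by the letters A to F. The treatments were calcium-free KSW (an incubation medium whose abbreviation the labels do not spell out), cytochalasin D and streptomycin. Calcium-free KSW and cytochalasin D had 5 time points each, T0 to T4, and streptomycin had 4, T0 to T3. Per the labels, the first 2 treatments were sampled at hourly points of recovery, whereas the streptomycin time points stand for different lengths of exposure, each sampled after the same recovery period, so they are not recovery times. The lengths of exposure, and whether T0 precedes or follows the trauma, are not given in the sources used here. The design text of the series speaks of 3 replicates and 2 conditions per time point, and the labels do not say which libraries would form a second condition. Nothing in the labels says that libraries of 1 group came from separate animals, so p-values measure the spread between these libraries, which may be technical. SDs, SEs and p-values of the main fits take the 6 libraries of a group as independent. The data show 3 letter pairs in a group (see Results), so these SEs and p-values may be too small.

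The values are counts of reads per gene model, deposited by the authors as 1 table of 23510 genes and 84 columns, with no scaling. Per the labels, RNA was extracted with a column kit and libraries were made by a published tag-based protocol, in which a gene's count does not grow with its length. Per the submitters' processing notes, Bowtie2 was used; its version and role, the genome build, the annotation, the counting tool, the use of strand and the treatment of duplicate or multiply mapped reads are not given in the sources used here. Reads of near-identical gene copies and of overlapping or antisense genes could therefore have been split or joined by the counting. Whether molecular identifiers entered the counts is likewise not known here. Every column matched the title of 1 sample, and 0 further sample columns were left unused. No 2 columns were identical; the highest correlation of log2 counts between 2 libraries was 0.913, and that pair differed by 1.55 times the chi-square expected from counting error per degree of freedom, so no library was treated as a repeat of another.

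The gene identifiers are numbered gene models (NVE) that the table does not pair with names. Of the 23510 identifiers, 0 matched the reference gene table used here (assembly jaNemVect1.1), so no gene is named by function, the 29 gene lists fixed beforehand were not tested, and at most 2 identifiers that rose and 2 that fell are printed per treatment. The rule fixed before the data were examined asked for an adjusted p under 0.05 for any change over time points and at the time point of the largest change, at least 5 of the 6 libraries of that time point on 1 side of the T0 median, average abundance above the median of the tested genes and an informative name, and it would have named more genes per treatment. With no names, the last condition was dropped and the largest 2 rises and 2 falls were taken, a reduction made after the identifiers were seen. Values of these genes in the other treatments were added after they had been chosen.

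Total counts per library ran from 194043 to 591692, with a median of 312264, which is shallow: 1 read equals 1.69 to 5.15 CPM (counts scaled to a common library size). Tests used edgeR 4.0.16 in R 4.3.3 on the deposited counts (filterByExpr by group, TMM scaling, estimateDisp, glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment and a threshold of 0.05. Each treatment was fitted on its own libraries with 1 mean per group; an F test over all later time points against T0 gave the count for any change, and contrasts gave the count for each time point. The T0 comparison of the treatments and the comparison of the calcium-free and cytochalasin D time courses came from 1 fit of all 84 libraries. Standard errors of log2 fold changes were derived from the F statistic of the contrast. CPM values given for genes are TMM-scaled. The direction of a call over several time points is the sign of the mean log2 change. For a gene with 0 reads in a group, the floor was 3 reads over the summed reads of the group; such floors and all intervals cover counting error only. Principal components used log2 CPM (prior count 2) of the 2000 most variable genes.

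Whether the letters pair libraries was checked by correlating deviations from group means across the genes above median abundance. Within a treatment, 0 of 26 pairs of groups had every same-letter correlation above 0.1, so letters were not treated as pairs there. Between treatments at T0, the lowest same-letter correlation was 0.224, 0.238 and 0.146 in the 3 pairs of groups, so for the T0 comparison the letters pair the libraries; this pairing comes from the data, as the labels say nothing of it. The number after S in a sample's title was taken here as a position on the sample sheet, which the labels do not state, and split at 146 and 147 into a low range of 44 libraries and a high range of 40. All calcium-free libraries were in the low range and all cytochalasin D libraries in the high range, whereas streptomycin had T0, T1 and 2 libraries of T2 in the low range and the others in the high range.

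The alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2 size factors in edgeR, no low-count filter, the letter as a replicate block, all 84 libraries in 1 fit, the sheet range as a term, robust estimation, letters A to C and D to F alone, and for correlations Spearman's rho and abundant genes alone. Leaving out libraries with totals far below the median was also planned, and 0 libraries met the limit set for it. The alternatives chosen after seeing the data were each library left out in turn, cytochalasin D without T4 D and T4 E, summed letter pairs, a term for the on-off pattern of the library, a block of time point and letter pair, a term for A to C against D to F, and the low sheet range alone. The adjustment of the reassignment tests of the correlations over their 3 comparisons was also added after their values were seen. The fits were tested on simulated counts with the real means, library sizes and dispersions and 200 changed genes. The simulated libraries vary independently, without the letter pairs found in the real ones, so the shares recovered and the shares of false calls below hold only for independent libraries. In the any-change test of cytochalasin D (4534 genes), 16.4% of genes changed by 1.5-fold at T4, 67.2% of those changed by 2-fold and 97.0% of those changed by 4-fold were recovered, with 7.69% of calls false. The calcium-free values (4336 genes) were 4.48%, 37.3% and 97.0%, with 7.07% of calls false, and the streptomycin values (2862 genes, T3) were 34.3%, 76.1% and 100%, with 6.67% of calls false. For the comparison of the 2 time courses (5132 genes), 0% of genes changed by 1.5-fold, 11.9% by 2-fold and 84.8% by 4-fold were recovered.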

Results

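Gene expression was measured in the oral disc and tentacles of adult Nematostella vectensis, a sea anemone, after 3 forms of trauma. Cytochalasin D blocks actin polymerisation, streptomycin is an aminoglycoside antibiotic that damages vertebrate hair cells, and calcium-free medium weakens adhesion that depends on calcium. Tag-based libraries were deposited as read counts for 84 samples in 14 groups of 6. Total counts ran from 217221 to 591692 in calcium-free KSW, from 272537 to 584632 in cytochalasin D and from 194043 to 354795 in streptomycin. Between 10708 and 17053 of the 23510 gene models were detected per library. The 10 genes with most reads took 29.9% of all reads. No untreated series was analysed here, so each comparison asks how a later time point differed from T0 of the same treatment.

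The first principal component held 9.38% of the variance and was higher at the last time point than at T0 in all 3 treatments. The treatments are not independent here, and the 6 libraries of a group form 3 letter pairs (A with D, B with E, C with F). Averaged over treatments, the score at T2 was -7.13 for B and E and 13.6 for C and F. The on-off pattern of T2 B and E (described below) recurred at T0 B and E, T1 A and D and T3 A and D. Scores there were -11.2, -8.99 and -2.89. That of T2 C and F recurred at T4 A and D (11.9) and T4 C and F (11.4). No pattern occurred at both T0 and T4, and at T3 only A and D had a T0 pattern. The rise from T0 to T4 thus cannot be told apart from a change of pattern. The mean score of the component rose from -12.7 ± 4.28 (SD, n = 6) at T0 to 9.22 ± 3.69 (SD, n = 6) at T4 in cytochalasin D. In calcium-free KSW it rose from -11.2 ± 5.43 to 10.8 ± 3.12 (SD, n = 6), and in streptomycin from -6.08 ± 4.98 at T0 to 9.16 ± 6.40 at T3 (SD, n = 6).

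**Figure D1:**
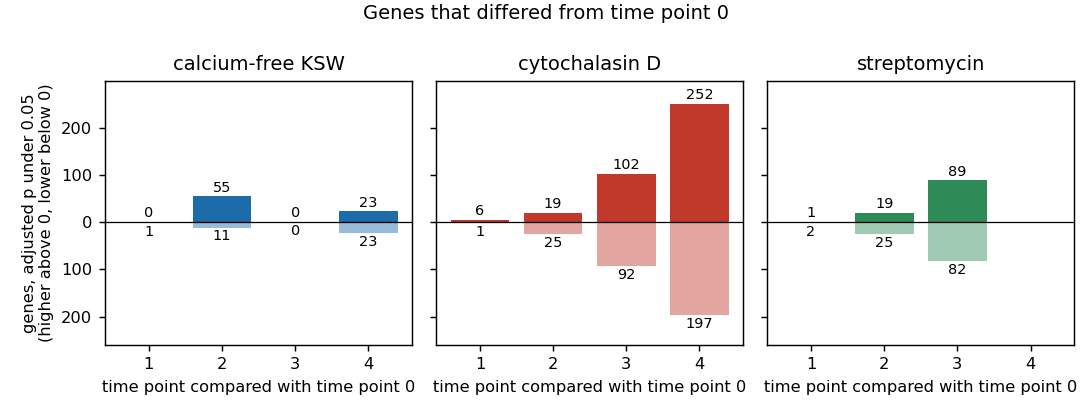
Genes with an adjusted p under 0.05 at each later time point against T0 (y axis, number of genes; higher above 0, lower below) for each treatment (x axis, time point; the streptomycin time points are exposure lengths, and streptomycin has no T4). In cytochalasin D the count rose from 7 at T1 to 449 at T4, in streptomycin from 3 at T1 to 89 higher and 82 lower at T3, and in calcium-free KSW it was 1, 66, 0 and 46.

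How expression moved during recovery from cytochalasin D was asked first. The gene NVE2343 rose from 204 ± 20.7 CPM at T0 (SD, n = 6) to 492 ± 59.7 at T1, 971 ± 326 at T2, 1100 ± 213 at T3 and 1356 ± 127.9 at T4 (SD, n = 6 each). Its log2 fold change at T4 was 2.73 ± 0.17 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.35e-13). NVE17523 rose from 13.6 ± 6.27 CPM at T0 to 105.9 ± 17.4 at T4 (SD, n = 6), a log2 fold change of 2.96 ± 0.29 (SE, edgeR adjusted p = 2.13e-08). Both genes were above the T0 median in 6 of 6 libraries at T4.

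Of the genes that fell, NVE24510 went from 198 ± 395 CPM at T0 to 4.34 ± 7.38 at T3 (SD, n = 6; log2 fold change -5.34 ± 1.27 SE, edgeR adjusted p = 0.0125). That fall rested on the T0 library F, at 869 CPM by library totals; without it the log2 fold change was -2.90 with an edgeR adjusted p of 0.211. NVE6912 had 0 reads in all 6 T4 libraries, and averaged 250 CPM of the library totals at T0. The floor of 3 reads over the 1979660 reads of the T4 group puts T4 at least 165.1-fold lower than that T0 mean (edgeR adjusted p = 0.0113). At T0 NVE6912 had over 10 reads in 4 libraries and 0 reads in libraries C and F. Across treatments it was on at T0 A and D, T0 B and E, T1 A and D, T2 B and E and T3 A and D. In every other time point and letter pair it was off, T1 B and E and T1 C and F included. Its absence at T4 thus follows which letter pairs were at T4, and cannot be read as a fall within a source. The call of NVE6912 ended without T4 D and T4 E (adjusted p = 0.0595, log2 fold change -9.52) and with letter pairs summed (0.111, -10.48), though the log2 fold change was -9.51 with all libraries. Summing also ended the call of NVE24510 (0.0592) at a log2 fold change of -5.42. A term for the on-off pattern of the library ended the call of NVE24510 (log2 fold change -0.98, adjusted p = 0.919). That term leaves T0 to B and E alone, so T0 F has no part in that contrast. For NVE6912 the term decides nothing, since the gene is part of the pattern.

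In total, 352 of the 4534 genes tested in cytochalasin D changed over the time points, 47.4% of them with a higher and the others with a lower mean than at T0. The largest change of 213 of these genes fell at T4, of 86 at T3, of 20 at T2 and of 33 at T1. The median size of the largest change was 1.00 on the log2 scale. Against T0, 7 genes differed at T1 (6 higher, 1 lower), 44 at T2 (19 higher, 25 lower), 194 at T3 (102 higher, 92 lower) and 449 at T4 (252 higher, 197 lower). With DESeq2 size factors the split at T1 was 6 higher and 4 lower, and in 1 fit of all 84 libraries lower genes were the more numerous at T2 (5 higher, 28 lower), T3 (33 higher, 74 lower) and T4 (110 of 245 higher). DESeq2 turned the balance at T2 (49 higher, 43 lower), and no low-count filter turned it at T4 (198 higher, 234 lower), so which direction held more genes depended on the setting. Summing letters A with D, B with E and C with F, an alternative chosen after the data were seen, left 213 genes at T4, and over the time points 0.668% of the 23510 gene models against 1.497% before. A term for the on-off pattern of the library, which overlaps with the time points, left 2 genes at T4, NVE2343 and NVE17523. The patterns of T0 A and D, T0 C and F and T4 B and E occurred in no other time point and letter pair. With this term, T0 thus rests on B and E alone, and T4 is tied to T0 only through T2. Calls lost with it may therefore reflect fewer libraries in the contrasts, and do not show that the pattern explains the calls. The T4 count was 142 without libraries T4 D and T4 E, left out because genes of the on-off pattern were at intermediate levels there (1 and 3 of 10), and 294 without T4 D alone. T4 A also had 1 of 10 at intermediate levels, so this does not set T4 D apart. The T1 count was 2 without T0 A and 27 without T0 B, and the T2 count was 15 without T0 F. The T3 calls, 0.825% of the 23510 gene models, were 0.472%, 0.527%, 0.510% and 0.540% without T0 A, T0 F, T3 C or T3 F.

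**Figure D2:**
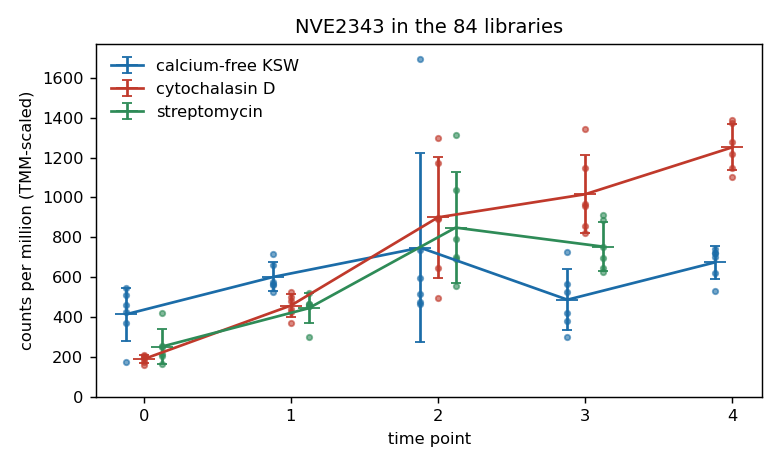
TMM-scaled expression of NVE2343 in CPM (y axis) at each time point (x axis) in the 3 treatments; points are libraries, and dashes with bars are the mean and SD of 6 libraries, all scaled together over the 84 libraries. In cytochalasin D the mean rose from 189 to 1251, in streptomycin from 251 at T0 to 849 at T2, and in calcium-free KSW it was 414 at T0 and 674 at T4.

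The streptomycin comparison asked how expression differed between exposure lengths, each followed by the same recovery. NVE2343 rose here too, from 230 ± 81.8 CPM at T0 to 770 ± 249 at T2 and 684 ± 115 at T3 (SD, n = 6), with a log2 fold change of 1.73 ± 0.20 at T2 (SE, edgeR adjusted p = 4.50e-06). NVE19155 rose from 44.9 ± 24.4 CPM to 125 ± 36.3 at T2 (SD, n = 6; log2 fold change 1.48 ± 0.29 SE, edgeR adjusted p = 0.00399). NVE16297 fell from 388 ± 218 CPM at T0 to 131 ± 39.1 at T1, 77.4 ± 34.6 at T2 and 55.3 ± 24.4 at T3 (SD, n = 6; log2 fold change at T3 -2.76 ± 0.33 SE, edgeR adjusted p = 3.68e-06). NVE16354 fell from 148.3 ± 76.5 CPM at T0 to 34.2 ± 10.1 at T3 (SD, n = 6; log2 fold change -2.09 ± 0.35 SE, edgeR adjusted p = 3.67e-04). All 4 genes lay on 1 side of the T0 median in 6 of 6 libraries.

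NVE16297 and NVE16354 also fell in cytochalasin D, with log2 fold changes at T4 of -3.08 ± 0.43 (SE, edgeR adjusted p = 4.26e-05) and -1.20 ± 0.31 (SE, edgeR adjusted p = 0.0124). Neither passed there with the on-off pattern as a term, which leaves T0 to B and E alone. In calcium-free KSW neither passed over the time points (mean log2 change -1.07 and -0.34, edgeR adjusted p = 0.175 and 0.386). NVE17523, named above for cytochalasin D, rose in streptomycin by 2.17 ± 0.30 on the log2 scale at T3 (SE, edgeR adjusted p = 2.66e-05). This rise did not pass with the sheet range as a term, where 0 genes were called higher at T3. In calcium-free KSW NVE17523 did not pass over the time points (mean log2 change 0.96, edgeR adjusted p = 0.128).

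Over the streptomycin time points 91 of 2862 tested genes changed, 34 higher and 57 lower than at T0. Against T0, 3 genes differed at T1 (1 higher, 2 lower), 44 at T2 (19 higher, 25 lower) and at T3 89 were higher and 82 lower (26 higher and 42 lower in 1 fit of all 84 libraries). The largest change of 69 of the 91 genes fell at T3. With letter pairs summed 26 genes passed over the time points (4 higher, 22 lower), 11 at T2, 39 at T3 and 0 at T1 by edgeR (305 at an unadjusted p under 0.05; DESeq2 on unsummed libraries called 8). With the on-off pattern as a term, where T0 rests on B and E alone, 9 passed over the time points and 13 at T3. With the sheet range as a term, 9 genes were past the threshold over the time points and 6, all lower, at T3, where the range and the exposure overlap; in the low range alone 0 genes differed at T1 by edgeR (243 at an unadjusted p under 0.05; DESeq2 over all streptomycin libraries called 8) and 4 at T2, which then has 2 libraries. NVE2343 and NVE16297 stayed past the threshold with that term (adjusted p = 0.00238 and 9.55e-04), NVE19155 and NVE16354 did not (0.162 and 0.0637, at log2 fold changes of 1.56 and -2.97, no smaller than before), and NVE19155 also did not with letter pairs summed (0.104, at 1.53) or with the on-off pattern as a term (0.513), where its log2 fold change was 0.78. The T3 calls, 0.727% of the 23510 gene models, were 0.451%, 0.404%, 0.379% and 0.459% without T0 A, T0 D, T3 B or T3 E, and the any-change count was 60 without T0 A.

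Recovery from calcium-free KSW was examined in the same way. NVE4372 rose from 20.6 ± 8.98 CPM at T0 to 103.04 ± 89.7 at T2 (SD, n = 6; log2 fold change 2.28 ± 0.53 SE, edgeR adjusted p = 0.0349). NVE17235 rose from 67.0 ± 25.9 to 262 ± 290 CPM at T2 (SD, n = 6; log2 fold change 2.00 ± 0.40 SE, edgeR adjusted p = 0.0261). NVE23459 fell from 156.4 ± 120 to 19.4 ± 13.9 CPM (SD, n = 6; log2 fold change -2.96 ± 0.67 SE, edgeR adjusted p = 0.0349), and NVE20024 from 131 ± 155.97 to 22.7 ± 11.8 CPM (SD, n = 6; log2 fold change -2.52 ± 0.52 SE, edgeR adjusted p = 0.0261). All 4 lay on 1 side of the T0 median in 6 of 6 libraries at T2. The T2 library F, which stood apart from its group, carried 725 CPM of NVE17235 against 108 to 210 in the other T2 libraries, by library totals. Without T2 F the adjusted p-values of NVE4372, NVE17235, NVE23459 and NVE20024 were 0.201, 0.109, 0.109 and 0.109, with log2 fold changes of 1.82, 1.14, -2.68 and -2.35; without T0 A they were 0.107, 0.0976, 0.0976 and 0.0627, and without T0 D 0.0805, 0.0719, 0.0805 and 0.0832, where NVE20024 had a log2 fold change of -1.57. The call of NVE4372 also ended without T0 C (0.0673), those of NVE4372 and NVE23459 without T0 E (0.0722 for both), and all 4 with letter pairs summed (0.244 for each, at log2 fold changes of 2.25, 2.07, -2.88 and -2.47). With the on-off pattern as a term the log2 fold changes of the 4 genes were 0.41, 0.61, -1.43 and -0.25, and none passed (adjusted p = 1.00 for each). That term leaves T0 to B and E alone.

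NVE17235 was also higher in the other treatments, by 1.57 ± 0.27 at T4 of cytochalasin D (log2, SE, edgeR adjusted p = 4.92e-04) and by 0.95 ± 0.21 at T3 of streptomycin (log2, SE, edgeR adjusted p = 0.00553). The streptomycin rise did not pass with the sheet range as a term, where 0 genes were called higher at T3. NVE23459 and NVE20024 changed over the cytochalasin D time points as well (mean log2 change -2.17 and -1.42, edgeR adjusted p = 0.0328 and 0.0286). In streptomycin neither passed (mean log2 change 1.19 and -0.50, edgeR adjusted p = 0.445 and 0.766). NVE4372 did not pass in cytochalasin D (mean log2 change 1.36, edgeR adjusted p = 0.245). With the on-off pattern as a term, which leaves T0 to B and E alone, none of NVE17235, NVE23459 and NVE20024 passed those tests in cytochalasin D.

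In all, 29 of 4336 genes changed over the calcium-free time points, 19 higher and 10 lower, with a median largest change of 1.62 on the log2 scale. The balance turned with a term for A to C against D to F (23 higher, 30 lower) and with the on-off pattern as a term (2 higher, 13 lower). The largest change of 19 of the 29 genes fell at T4, of 8 at T2, of 1 at T1 and of 1 at T3. The 4 genes named above all had their largest change at T2, so they do not stand for most of the calls. Against T0, 1 gene differed at T1 (lower), 66 at T2 (55 higher, 11 lower), 0 at T3 (351 at an unadjusted p under 0.05; 6 with DESeq2) and 46 at T4 (23 higher, 23 lower; 36 higher and 18 lower with DESeq2, and 77 of 198 lower in 1 fit of all 84 libraries). Without the T2 library F the counts were 2 at T1, 0 at T2 (edgeR), 54 at T3 and 326 at T4, and the genes that changed over the time points went from 0.123% to 0.630% of the 23510 gene models. The any-change count was 0 by edgeR without T0 A, T4 B, T4 D or T4 F and with letter pairs summed (650 at an unadjusted p under 0.05 when summed; DESeq2 on all libraries called 57 higher and 47 lower), and leaving out any of 16 of the 30 libraries moved it by over 1.5 times.

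The treatments were compared at T0 to see whether they differed there. Whether T0 precedes or follows the trauma is not known, and in streptomycin T0 stands for a length of exposure. The T0 groups are thus not known to be starting states. Streptomycin T0 libraries had 12552 ± 1148 genes detected, against 14450 ± 1411 in calcium-free KSW and 14387 ± 619 in cytochalasin D (SD, n = 6). Whether this adds to the T0 differences was not tested. At T0 3.06% of 5132 genes differed between the 3 treatments. Leaving out the calcium-free library T2 F, not a T0 library, moved the share from 0.668% to 1.21% of the 23510 gene models. Against streptomycin, 48 genes were higher and 57 lower in calcium-free KSW; against cytochalasin D, 24 were higher and 34 lower in calcium-free KSW; and 19 were higher and 18 lower in cytochalasin D than in streptomycin. NVE2343 averaged 414 ± 134 CPM at T0 in calcium-free KSW, 189 ± 19.1 in cytochalasin D and 251 ± 88.4 in streptomycin (SD, n = 6, all libraries scaled together). With the time point and letter pair as a block, chosen after the data were seen, 233 genes differed, which include all but 1 of those called without the block; the 3 pairs then gave 0.787%, 0.476% and 0.208% of the 23510 gene models, against 0.447%, 0.247% and 0.157% without it. Cytochalasin D lay in another sheet range than the other T0 groups, so the treatment and the range cannot be told apart in the pairs that include it.

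The time courses of calcium-free KSW and cytochalasin D were compared directly, since both were sampled during recovery. A single gene of 5132 differed, NVE2343 (edgeR adjusted p = 3.04e-06; 362 genes had an unadjusted p under 0.05). At T4 it had risen by 0.71 ± 0.22 in calcium-free KSW and by 2.73 ± 0.23 in cytochalasin D on the log2 scale (SE), a difference of -2.02 ± 0.32 (SE, calcium-free minus cytochalasin D). Its means were already apart at T0, at 414 CPM in calcium-free KSW and 189 in cytochalasin D, against 674 and 1251 at T4. The difference in rise thus includes the T0 difference, and the 2 treatments lay in different sheet ranges. In the calcium-free libraries fitted alone the rise of NVE2343 did not pass (adjusted p = 0.194). DESeq2 called 6 genes for this comparison, the fit with no low-count filter 19, and edgeR without the calcium-free T2 library F 5.

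**Figure D3:**
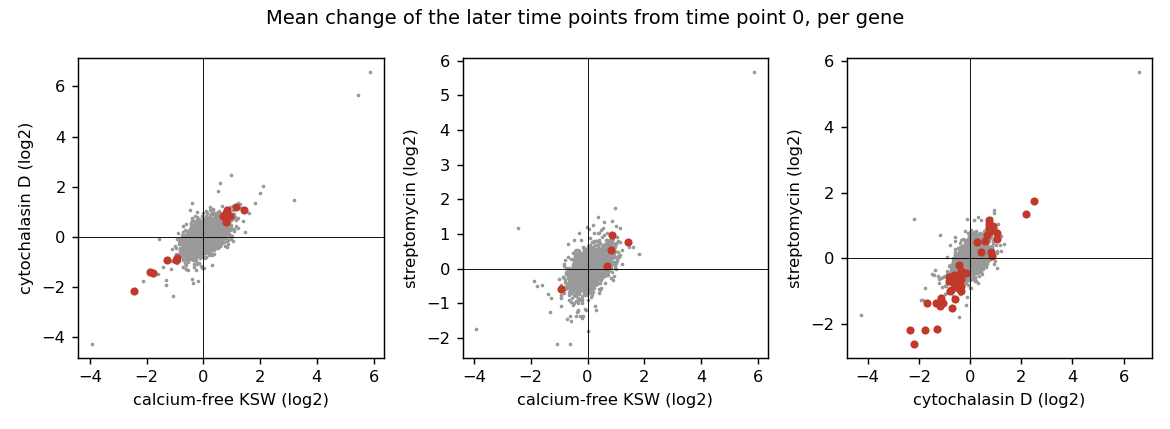
Mean log2 change of the later time points from T0 for each gene in 2 treatments (x and y axes, log2 fold change); grey points are genes tested in both, and red points are genes past the threshold for any change in both. Pearson's r across genes was 0.629, 0.561 and 0.630 from left to right, and 0 genes were called in opposite directions.

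The changes were compared across treatments to see how far they coincided. Across 4081 genes, the mean later-minus-T0 changes of calcium-free KSW and cytochalasin D had a Pearson's r of 0.629 and a Spearman's rho of 0.498. For calcium-free KSW and streptomycin r was 0.561 and rho 0.507 (2846 genes), and for cytochalasin D and streptomycin 0.630 and 0.518 (2855 genes); genes are not independent replicates. Cytochalasin D and streptomycin shared 15 genes called higher in both (1.73 by chance, Fisher's exact test, adjusted p = 4.57e-11) and 30 called lower in both (2.46 by chance, adjusted p = 9.19e-27). Calcium-free KSW and cytochalasin D shared 9 higher (0.745 by chance, adjusted p = 2.31e-08) and 6 lower (0.346 by chance, adjusted p = 3.38e-07). Calcium-free KSW and streptomycin shared 4 higher (0.203 by chance, adjusted p = 4.35e-05) and 1 lower (0.155 by chance, adjusted p = 0.145). Of the 2841 genes tested in all 3 treatments, 52 were called in at least 2, and all 52 moved 1 way in those, a share whose value without any effect was not computed; 5 were called in all 3, of which 4, NVE17235 among them, were higher and 1 was lower. Libraries of the same time point and letter pair deviated from their groups together across treatments, so the treatments were not independent samples of the time points, and the chance values above leave this sharing out. With sets of libraries reassigned jointly to time points, the r of log2 CPM changes had a median of 0.378, 0.341 and 0.352 against 0.565, 0.449 and 0.489 observed, and it reached the observed value in 2.5%, 14.9% and 10.4% of 1000 assignments for the 3 pairs in the order above.

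**Figure D4:**
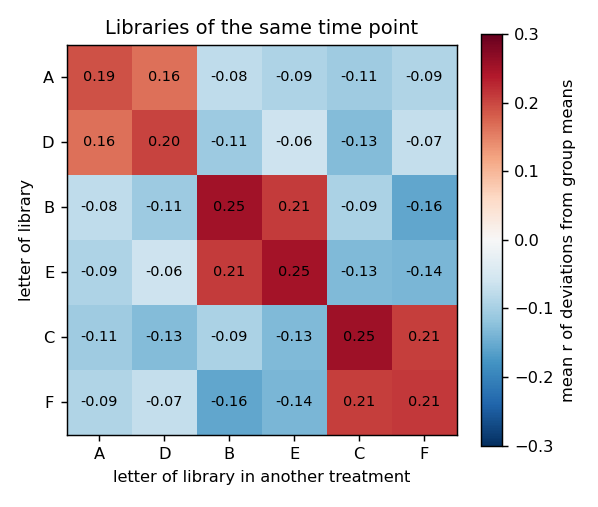
Mean correlation of deviations from the group mean between libraries of the same time point in different treatments, by the letter of each library (both axes, letters A to F ordered by pair). Libraries with the same letter (mean r 0.227) or the partner letter (0.194) deviated together, and those with other letters did not (-0.0915 and -0.118).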

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

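The test of on-off genes in calcium-free T2 F was chosen after the result was seen. Over 4 measures (total count, genes detected, share of the 10 top genes and median correlation with the group) in 14 groups, 56 sets of 6 libraries were examined, and 6 held a library far from the others by Dixon's ratio (at its 95% critical value); chance gives about 5% of such sets. Cytochalasin D T2 B had a total of 584632 reads (nearest library 364534), 17053 genes detected (nearest 14605) and 17.5% of reads in its 10 top genes (nearest 26.6%). Cytochalasin D T0 B had 24.9% of reads in its 10 top genes (nearest 29.4%). Calcium-free T1 F had 13470 genes detected (nearest 14901).

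Calcium-free T2 F had a median correlation of 0.647 with the other libraries of its group (nearest 0.881). It had 248 genes above 100 CPM and above 2 times every other library, where no other library had more than 4, and these genes took 11.1% of its reads against a median of 2.45% in the others. Library depth was argued against, since 254 such genes were found after thinning to 297641 reads. A library from a set with another on-off pattern was argued against too: its on-off genes had 0 mismatches with its own time point and letter pair and at least 3 with sets of another pattern, although T4 A and D and T4 C and F share its pattern and stay open. A source shared by the libraries of T2 C and F was argued against. Calcium-free T2 C, cytochalasin D T2 C and F and streptomycin T2 C and F each had 0 such genes. Handling of this library, or a source not shared with those, may explain the difference. It was not tested, as the design gives no group to which a biological explanation could be tied.

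NVE2343 was the gene whose time course differed between calcium-free KSW and cytochalasin D (edgeR adjusted p = 3.04e-06).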

How the results depend on the processing

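The settings chosen only after results were seen were summed letter pairs, the on-off pattern, A to C against D to F, the low sheet range alone, the leaving out of libraries and the block of time point and letter pair. Of 187 recalculated counts and correlations, 74 stayed within 1.5 times (counts) or 1 SD over letters left out (correlations), 69 fell below, 38 rose above and 6 correlations moved, with 0 changes of sign among correlations. The balance of higher against lower genes is not part of these numbers, and it turned in some settings (cytochalasin D T4 in 1 fit of all 84 libraries: 110 of 245 higher). Of 68 recalculated changes of named genes, 51 stayed past the threshold, 17 did not and 0 turned direction; the on-off term decides nothing for NVE6912, which is part of the pattern. The settings run for named genes were DESeq2 size factors, the letter block, summed pairs, the on-off term and 1 fit of all 84 libraries. Libraries left out and, in streptomycin, the sheet range were run too. NVE2343 and NVE17523 in cytochalasin D and NVE2343 and NVE16297 in streptomycin passed under each of these. Named genes were not recalculated with DESeq2 itself, no low-count filter or robust estimation. Nor were they with letters A to C or D to F alone, their term or the low sheet range alone. Small changes were often missed: 4.48%, 16.4% and 34.3% of simulated 1.5-fold changes were recovered in calcium-free KSW, cytochalasin D and streptomycin. One read is 1.69 to 5.15 CPM. Recovery did not follow depth across treatments, as median totals were 319052, 346511 and 266808 in that order. The common coefficient of variation between libraries, from fits of the same libraries, was 31.6%, 24.3% and 21.5% in that order, and recovery rose as it fell. The sets of simulated genes also differed (4336, 4534 and 2862 genes), and the effects of spread and of gene set were not separated. Planned removal of libraries with totals far below the median concerned 0 libraries, and the gene list tests were not run, as no identifier matched a name. Summed pairs and 3-letter fits have fewer libraries, and the pattern and sheet terms overlap with the time points. The pattern term also leaves T0 to B and E alone. Otherwise the cause of the differences between settings was not tested. Calls are given below as percent of the 23510 gene models, where 1 gene is 0.00425%.

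With the settings of the report the calls were 0.123% over the time points, 0.00425% at T1, 0.281% at T2, 0% at T3 and 0.196% at T4 in calcium-free KSW, 1.497% over the time points, 0.0298% at T1, 0.187% at T2, 0.825% at T3 and 1.91% at T4 in cytochalasin D, 0.387% over the time points, 0.0128% at T1, 0.187% at T2 and 0.727% at T3 in streptomycin, 0.00425% for the difference between the time courses, and 0.668% between treatments at T0. With DESeq2 the calls were 0.442% over the time points, 0.00851% at T1, 0.583% at T2 and 0.0255% at T3 in calcium-free KSW, 0.0936% at T1 and 0.391% at T2 in cytochalasin D, 0.0340% at T1 in streptomycin, and 0.0255% for the difference between the time courses. With DESeq2 size factors in edgeR the calls were 0.455% at T2 in calcium-free KSW. With no low-count filter the calls were 2.49% over the time points, 0.153% at T1, 1.52% at T2, 0.230% at T3 and 0.872% at T4 in calcium-free KSW, 2.77% over the time points, 0.557% at T1 and 0.761% at T2 in cytochalasin D, 1.10% over the time points, 0.179% at T1 and 0.476% at T2 in streptomycin, and 0.0808% for the difference between the time courses. With robust estimation the calls were 0.0681% over the time points in calcium-free KSW. In 1 fit of all 84 libraries the calls were 2.31% over the time points, 0% at T1, 2.28% at T2, 0.0255% at T3 and 0.842% at T4 in calcium-free KSW, 0.966% over the time points, 0.0128% at T1, 0.455% at T3 and 1.04% at T4 in cytochalasin D, and 0.217% over the time points, 0.00425% at T1, 0.0595% at T2 and 0.289% at T3 in streptomycin. With letters A to C alone (3 libraries per group) the calls were 0% over the time points, 0% at T1, 0% at T2 and 0.00425% at T4 in calcium-free KSW, 0.153% over the time points, 0% at T1, 0.0978% at T2, 0.119% at T3 and 0.123% at T4 in cytochalasin D, and 0.0425% over the time points, 0% at T1, 0.0128% at T2 and 0.0808% at T3 in streptomycin. With letters D to F alone the calls were 0% over the time points, 0% at T1, 0.00851% at T2 and 0% at T4 in calcium-free KSW, 0.808% over the time points, 0.383% at T1, 0.315% at T3 and 0.991% at T4 in cytochalasin D, and 0.0170% over the time points, 0% at T1, 0.0425% at T2 and 0.0936% at T3 in streptomycin. With the sheet range as a term the calls were 0.0383% over the time points, 0.0298% at T2 and 0.0255% at T3 in streptomycin. In the low sheet range alone the calls were 0% at T1 and 0.0170% at T2 in streptomycin. With letter pairs summed the calls were 0% over the time points, 0% at T1, 0% at T2 and 0% at T4 in calcium-free KSW, 0.668% over the time points, 0.0170% at T1, 0.123% at T2, 0.430% at T3 and 0.906% at T4 in cytochalasin D, and 0.111% over the time points, 0% at T1, 0.0468% at T2 and 0.166% at T3 in streptomycin. With a term for the on-off pattern the calls were 0.0638% over the time points, 0% at T1, 0% at T2 and 0% at T4 in calcium-free KSW, 0.00851% over the time points, 0.00425% at T1, 0.00851% at T2, 0.00851% at T3 and 0.00851% at T4 in cytochalasin D, and 0.0383% over the time points, 0% at T1, 0.0213% at T2 and 0.0553% at T3 in streptomycin. With a term for A to C against D to F the calls were 0.225% over the time points in calcium-free KSW, 0.0808% at T1 and 0.510% at T2 in cytochalasin D, and 0.00425% at T1 in streptomycin. Without T4 D and T4 E the calls were 0.604% at T4 in cytochalasin D.

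With the letter as a replicate block, the calls were 0.298% over the time points, 0% at T1, 0.166% at T2, 0.0425% at T3 and 0.328% at T4 in calcium-free KSW, 2.03% over the time points, 0.179% at T1, 0.510% at T2, 1.20% at T3 and 2.20% at T4 in cytochalasin D, 0.447% over the time points, 0.0128% at T1, 0.179% at T2 and 0.749% at T3 in streptomycin, 0.00851% for the difference between the time courses, and 0.761% between treatments at T0. Within treatments the letters did not pair the libraries, so this block is only a hint from the data (with it, calcium-free calls over the time points were 33 higher and 37 lower): the best match at other time points of the treatment had the same letter for 27 of 84 libraries, against 14 from the share of that letter among the candidates. Libraries of 1 treatment at different time points had a mean r of 0.0878 with the same letter, 0.0597 with another letter of the same 3 (A to C or D to F) and -0.0783 with a letter of the other 3 that is not the partner. With time point and letter pair as a block, 0.0128% differed between the time courses. Without calcium-free T2 F, 1.21% differed between treatments at T0 and 0.0213% between the time courses.

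Spearman's rho of the changes was 0.498 for calcium-free KSW and cytochalasin D, 0.507 for calcium-free KSW and streptomycin, and 0.518 for cytochalasin D and streptomycin; Pearson's r over genes above median abundance was 0.686, 0.699 and 0.719.

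With each library left out in turn, calcium-free calls ranged from 0% to 0.630% over the time points, 0% to 0.00851% at T1, 0% to 1.12% at T2, 0% to 0.230% at T3 and 0.0595% to 1.39% at T4, by edgeR. The highest values over the time points, at T3 and at T4 came without T2 F, and the lowest at T4 without T4 C. Cytochalasin D calls ranged from 1.18% to 1.68% over the time points, 0.00851% to 0.115% at T1, 0.0638% to 0.234% at T2, 0.472% to 0.902% at T3 and 1.25% to 2.10% at T4. The lowest came without T0 F at T2, without T0 A at T3 and without T4 D at T4. Streptomycin calls ranged from 0.255% to 0.464% over the time points, 0% to 0.0298% at T1, 0.106% to 0.272% at T2 and 0.379% to 0.778% at T3. The lowest came without T0 A over the time points, without T0 D at T2 and without T3 B at T3.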

Other observations

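The tests of letters dealt by chance, of A to C against D to F and of letter pairs kept together, other than over the time points of cytochalasin D and streptomycin, were chosen after results were seen, and the other tests here were written down before their values were seen, though the patterns came from these data. Changes from T0 were compared between treatments time point by time point, a comparison not described above. Matched here means the same time point number, where libraries of the same letter pair deviated together across treatments. That sharing could raise the matched values, so they do not show a shared time course. For calcium-free KSW and cytochalasin D the correlation across genes was 0.487 at T1, 0.568 at T2, 0.531 at T3 and 0.657 at T4, and between unmatched time points it ran from 0.181 (T3 with T1) to 0.547 (T2 with T4), so the 2 overlapped; genes are not independent replicates. For the other pairs of treatments an unmatched value exceeded a matched one: calcium-free T2 with streptomycin T3 gave 0.536 against 0.449 at T2, and cytochalasin D T2 with streptomycin T3 gave 0.579 against 0.554 at T2. Streptomycin time points are exposure lengths, so an equal number there does not match a recovery time. A set of 10 genes, NVE6912 among them, was either on (at least 30 CPM) or off (at most 1 read) in nearly every library. Of 814 such values, 1 differed from the majority of its time point and letter pair, across treatments: NVE22422 had 40 reads in cytochalasin D T4 E, a library with 3 of the 10 genes at intermediate levels.

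Libraries of the same time point and letter pair (A with D, B with E, C with F) deviated from their groups together across treatments: for 79 of 84 libraries the best match had the same or the partner letter. Letters dealt by chance were argued against (1 of 200 shuffles as high, the real one included; highest other 48), as was library depth (79 after thinning to 194043 reads; highest other 47). The sheet range was argued against as the whole cause, since in library pairs from different ranges the same or partner letters exceeded the others by 0.301 in mean r (0.2002 against -0.101). A shared source of the libraries of 1 letter pair and time point, such as the same animals or genotypes, may explain the pattern: sets at different time points with the same on-off pattern correlated by 0.328 over the other genes against -0.0366 for sets with different patterns, a difference of 0.365 (exact permutation test, 1-sided, p = 0.00103, 7776 assignments). Whether the sources are animals, clones or pools is not stated in the labels, and stays open.

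Such sources, if dealt to time points, could produce changes that recur across treatments. In joint reassignments of sets to time points, 2.5% of 1000 gave a correlation as high as the 0.565 of calcium-free KSW and cytochalasin D (p = 0.025 by permutation, adjusted over 3 comparisons 0.075), which argued against sources alone before adjustment and left them open after it. For calcium-free KSW and streptomycin 14.9% of 1000 were as high as 0.449, and for cytochalasin D and streptomycin 10.4% of 1000 as high as 0.489, so shared sources dealt to time points stay open there. With letter pairs as units dealt to time points, 1 of 100 assignments, the real one, called as many genes as the 352 of cytochalasin D (highest other 249), which argued against this as the whole cause there, and 5 of 100 called as many as the 91 of streptomycin (0.387% of the 23510 gene models; highest other 0.608%), so for streptomycin this explanation stays open. The biological explanations that the design names, recovery for calcium-free KSW and cytochalasin D and the length of exposure for streptomycin, stay open and were not tested.

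Other assignments of the single libraries were drawn 100 times, the real one included. They took the libraries of a letter pair as independent, with no adjustment over the counts tested. Within that limit chance could be excluded over the time points for calcium-free KSW (29 genes; highest other 10; 1 assignment as large), cytochalasin D (352; 18; 1) and streptomycin (91; 7; 1), and for the treatments at T0 (3.06% of 5132 genes; highest other 14 genes; 1). It could be excluded at T1, T2, T3 and T4 of cytochalasin D (7, 44, 194 and 449 genes; highest others 10, 13, 2 and 9; 2, 1, 1 and 1 assignments as large) and at T1, T2 and T3 of streptomycin (3 and 44 genes, and 89 higher with 82 lower; highest others 3, 2 and 1; 2, 1 and 1). In calcium-free KSW it could be excluded at T1, T2 and T4 (1, 66 and 46 genes, with 2, 3 and 2 as large). The highest others were 1 and 387 genes and, at T4, 0.476% of the 23510 gene models against the real 0.196%. What gave the split with 387 calls was not tested. Chance could not be excluded for the number of genes that differed between time courses (1 gene, highest other 36, 14 as large). A draw with any 1 gene called is as large, so the draws do not weigh the size of the NVE2343 difference. At calcium-free T3 the draws decide nothing, since with 0 genes called by edgeR (351 at an unadjusted p under 0.05, 6 by DESeq2) all 100 are as large by construction (highest other 76).

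With letter pairs kept together, chance could not be excluded for several of these counts. In calcium-free KSW 26 of 100 assignments called as many genes over the time points, 40 at T1, 7 at T2 and 6 at T4 (highest others 413, 510, 475 and 213). In cytochalasin D 23 did so at T1 and 5 at T2 (highest others 0.230% and 0.587% of the 23510 gene models), and in streptomycin 5 over the time points and 40 at T1 (highest others 0.608% and 0.519%). Under 5 of 100 assignments were as large with pairs for cytochalasin D over the time points (1), at T3 (2, highest other 266) and at T4 (1, highest other 205). For streptomycin 4 were as large at T2 (highest other 0.744%, against the real 0.187%) and 1 at T3 (0.642%, against 0.727%). These shares were not adjusted over the counts tested. In streptomycin they also leave out the sheet range, and with it as a term 7 genes were called at T2 and 6 at T3. With libraries exchanged between treatments within their letter pair, 1 assignment, the real one, was as large at T0 (highest other 22). For the number of genes that differed between time courses 12 were as large (highest other 28), so chance could not be excluded for that number.

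Letters A to C differed from D to F in 281 genes over all libraries (47.3% of them higher), and the other 9 splits of the letters gave 0 to 92; 10 splits are too few for a share under 0.05, and 1 was as large. Fitted alone, 118 genes differed in calcium-free KSW, 429 in cytochalasin D and 27 in streptomycin. The differences correlated across genes by 0.379 between calcium-free KSW and cytochalasin D, -0.137 between calcium-free KSW and streptomycin and -0.235 between cytochalasin D and streptomycin. The series text speaks of 3 replicates and 2 conditions per time point, and the labels do not say whether A to C and D to F are those conditions; if they are, each mean and SD of 6 libraries given here pools 2 conditions of 3 libraries.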
